A study of Homo sapiens with 8 samples.

How the data were processed

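Frozen cells of placental biopsies were thawed and loaded for droplet-based single-cell RNA-seq (10x Genomics 3' chemistry, v3), after enzymatic digestion, lysis of red blood cells and straining, per the labels' protocols. The submitters' processing notes name Cell Ranger 4.0.0 and the genome build hg38. The deposited file is a table with 1 row per cell that gives the cell barcode, library, placenta, site, cell class and cluster number. Its column names are those of an export from Seurat. How the authors filtered cells, removed doublets, integrated libraries, clustered and named the classes is not given in the sources used here. The values in the deposited table are therefore labels, and the cells per class and library were counted from them. Each cluster number carries 1 class name. Gene expression, UMIs, genes per cell and mitochondrial shares were not used here, so the comparisons of these planned for each library and class were not made, no gene or marker is reported, and class names could not be checked against markers. RNA depth per cell is unknown.

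Libraries were grouped by their labels into the accreta invasive site (n = 3), accreta opposite site (n = 2) and control (n = 3). The group, replicate numbers, tests, naming rule and first list of alternatives were fixed before the data were examined. The number of cells per library, 122 to 12307, sets the precision of each share. Shares of single libraries carry 95% Wilson intervals, and a class with 0 cells is given the limit that 3 cells would allow. Classes were put in 6 lineages by the words of their names. The 3 classes named Decidua were read as the decidual part of the planned stromal and muscle lineage, which holds no other class, so it is called decidua here.

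The main test was limma 3.58.1 in R 4.3.3 on logit shares, the log of (cells of the class + 0.5) over (cells of all other classes + 0.5). All 8 libraries entered 1 fit with group as the only term, empirical Bayes with robust estimation, and Benjamini-Hochberg adjustment over classes in each comparison at a threshold of 0.05. This fit borrows the spread across classes, so Decidua 2, whose own residual SD was 0.572 on the logit scale, was tested against a larger one. The comparisons of both accreta sites use the same control libraries. Wilson intervals were computed with scipy 1.17.1. Two-sided exact permutation tests of the difference in mean share were run beside the limma fit, over every relabelling. These have 20 relabellings for 3 against 3 and 10 for 3 against 2, and cannot give a p under 0.10. The main test of the endothelial share at the invasive site against control was the exact test, with limma as an alternative. Exact tests between the sites relabelled libraries freely and so ignored the pairs. In each comparison the named classes are those past the threshold, filled up to 8 by the largest absolute difference in log odds, and every lineage is named. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

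The fit was tested on simulated data, 200 data sets of 10 classes with the real cell numbers and spread, in which 1 class was changed between invasive site and control. It recovered 4.5% of 5-fold changes in odds, 26.0% of 20-fold and 57.5% of 100-fold changes, and called 0.667% of classes when nothing was changed. It also called 1.06%, 1.56% and 6.61% of the unchanged classes beside 5-fold, 20-fold and 100-fold changes of another class. With a spread 0.25 times that observed it recovered 80.5% of 5-fold changes, and called 5.0%, 30.9% and 43.2% of the unchanged classes in the same order. The unchanged classes were not altered themselves, but their shares moved as the altered class took up or gave up cells. Calls among them beside a changed class therefore do not give a rate of false calls.

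Invasive and opposite site libraries with the same replicate number come from the same placenta by the series design. Their deviations from the group means over classes correlated at 0.597 for replicate 4 and -0.127 for replicate 6. Invasive site replicate 5 and opposite site replicate 6, from different placentas, correlated at 0.578. With 2 opposite site libraries, the deviations from their mean mirror each other. These values therefore cannot show how alike libraries of the same placenta are. Alternatives planned for class shares were the arcsine square root, 1 or 0.1 in place of 0.5, classes of at least 100 cells, only the groups compared, shares within the lineage, the 25 numbered clusters, placentas as a block, and each library left out in turn. For the endothelial share they were other denominators, the pooled share and limma. Alternatives added after the data were seen were leaving out the 2 libraries under 500 cells, leaving out cells whose barcode and cluster recur in another library, the library set as a covariate, centred log ratios, a fixed placenta term, library weights, no erythrocytes and non-robust estimation. The library sets came from the barcodes. A pair of libraries was linked when it shared at least 10 barcodes of which over 50% carried the same class in both, which linked 4 libraries and left the other 4 as the second set. To test shared barcodes, each barcode was counted once and its classes or clusters were set against 10000 random draws from the makeup of each library. Clusters were also tested within their class by the same limma fit.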

Results

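Placenta accreta spectrum is a disorder in which the placenta attaches too deeply to the wall of the uterus. Single-cell RNA-seq libraries were made from biopsies of accreta and control placentas. In accreta placentas, biopsies came from where invasion was deepest (the invasive site) and from a normally attached place across from it (the opposite site). The design compares both accreta sites with control placentas, and the series title names endothelial cells, which line blood vessels. The 8 libraries used here were 3 from the invasive site, 2 from the opposite site and 3 from controls, each control from a different placenta. Replicates 4 and 6 of both sites came from the same 2 placentas, and the opposite site of replicate 5 was not analysed here. By their labels, accreta biopsies of both sites held placenta, decidua and myometrium, whereas control biopsies held placenta and decidua.

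Each of the 31406 cells in the deposited table carries its library, 1 of 10 named cell classes and 1 of 25 cluster numbers. The unit of every comparison is the share of a library's cells that falls in a class. Invasive site libraries held 7951, 122 and 645 cells for replicates 4, 5 and 6. Opposite site libraries held 4039 and 5018 cells for replicates 4 and 6. Control libraries held 949, 375 and 12307 cells for replicates 2, 3 and 7. The largest library thus had 100.9 times the cells of the smallest, around a targeted recovery of 6000 cells. A class with no cell in invasive site replicate 5 could still make up to 2.46% of that sample, against 0.0244% in control replicate 7. Wilson intervals and these limits cover counting error only. The p-values rest on the spread between libraries, which limma shares across classes. Libraries of the same placenta are treated as independent in the main fit.

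Trophoblast, endothelial, decidual and immune cells were present in all 3 groups, but libraries of the same group differed widely. Trophoblast, the epithelium of the placenta, was the leading lineage by mean share in each group, but at both accreta sites this turned on single libraries. Without invasive site replicate 5 the mean at that site was 29.1% trophoblast and 36.8% endothelial, and without replicate 6 it was 38.1% and 39.4%. In opposite site replicate 4 trophoblast made up 28.8% and myeloid cells 29.6%. Cytotrophoblasts, the progenitors of the trophoblast, made up 55.0% of opposite site replicate 6 (95% Wilson interval 53.7 to 56.4%) and 4.68% of opposite site replicate 4 (4.07 to 5.37%). Extravillous trophoblasts, which migrate into the decidua, made up 62.4% of control replicate 3 (57.4 to 67.2%) and 1.99% of control replicate 7 (1.76 to 2.25%). Erythrocytes made up 11.0% of opposite site replicate 6 (10.1 to 11.9%) and at most 0.310% of the cells seen in each of the other libraries, with none among the 122 cells of invasive site replicate 5, which allows up to 2.46%. Red cell lysis was part of the preparation. In invasive site replicate 5 only 5 of the 10 classes were seen.

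**Figure D1:**
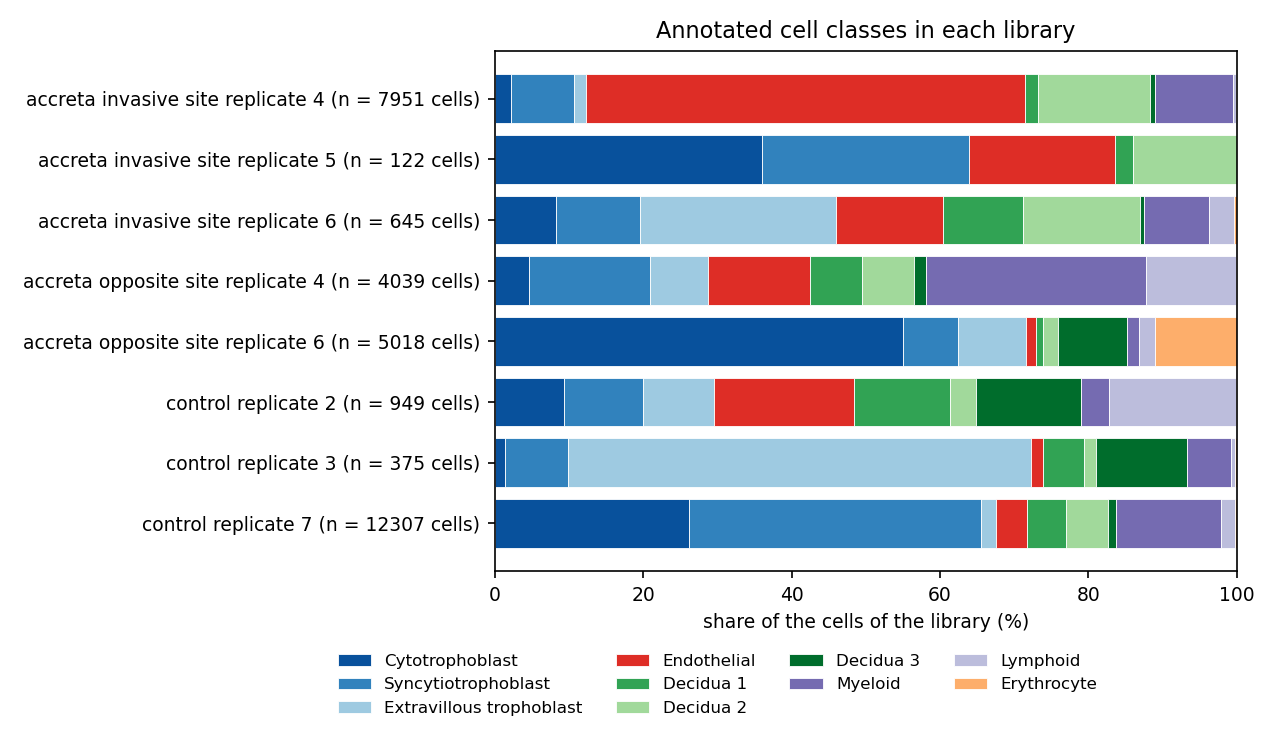
Each bar is 1 library, with its number of cells, and the coloured segments are the shares of the 10 cell classes in percent of its cells. Endothelial cells (red) fill 59.2% of invasive site replicate 4, and cytotrophoblasts (dark blue) fill 55.0% of opposite site replicate 6.

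Endothelial cells and the class named Decidua 2 had higher mean shares at the invasive site than in controls, and Decidua 3 had a lower one, but no class passed the test. The decidua is the lining of the uterus in pregnancy, and the table numbers its classes without further names. Endothelial cells made up 31.1% ± 24.5 (SD, n = 3) of invasive site libraries and 8.24% ± 9.29 (SD, n = 3) of control libraries. Decidua 2 made up 14.9% ± 0.946 (SD, n = 3) at the invasive site, within 13.9 to 15.8%, and 3.59% ± 2.04 (SD, n = 3) in controls, within 1.60 to 5.68%. Decidua 3 made up 0.419% ± 0.398 (SD, n = 3) at the invasive site and 9.19% ± 7.10 (SD, n = 3) in controls.

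By observed shares, the invasive site and control libraries did not overlap in 2 of the 10 classes, Decidua 2 and Decidua 3, and chance gives 10% of classes for 3 against 3. For Decidua 3, counting error alone could make the groups overlap. The absence of these cells from the 122 cells of invasive site replicate 5 allows up to 2.46%. Control replicate 7 held 1.06% (0.898 to 1.26%). Invasive site replicate 4 held 0.792% (0.620 to 1.01%), which overlaps that interval. Invasive site replicate 6 held 3 in 645 cells (0.158 to 1.36%), which overlaps it as well. Decidua 2 and Decidua 3 both had the smallest two-sided p an exact permutation test allows here, 0.10, which was 0.50 after adjustment over the classes. With limma on logit shares, 0 of 10 classes passed an adjusted p of 0.05, and 1 had an unadjusted p under 0.05. That class was Decidua 3, with a difference in log odds of -2.42 (SE 1.10) and an adjusted p of 0.356. Its cells stood in different clusters in the control libraries. Cluster 22 held 44 of the 46 in control replicate 3 and none in control replicates 2 and 7. Cluster 15 held 105 of the 135 in control replicate 2. It made up 11.1%, 0.533% and 0.894% of all cells in control replicates 2, 3 and 7. At the invasive site it made up 0.667% in replicate 4 and was not seen in replicates 5 and 6. The limma estimate for endothelial cells was 1.94 (SE 1.12), an odds ratio of 6.94 with a 95% confidence interval of 0.698 to 69.0 and an adjusted p of 0.415. For Decidua 2 it was 1.65 (SE 1.05), an odds ratio of 5.23 with an interval of 0.616 to 44.4 and an adjusted p of 0.415. Extravillous trophoblasts made up 9.36% ± 14.9 (SD, n = 3) at the invasive site and 24.6% ± 32.9 (SD, n = 3) in controls. Lymphoid cells made up 1.29% ± 1.85 (SD, n = 3) against 6.51% ± 9.26 (SD, n = 3), a control mean set by control replicate 2 (17.2%) that was 1.17% without it. For extravillous trophoblasts the invasive site mean was 0.780% without invasive site replicate 6, and the control mean was 5.74% without control replicate 3. Myeloid cells made up 6.42% ± 5.61 (SD, n = 3) against 7.91% ± 5.54 (SD, n = 3). Decidua 1 made up 4.97% ± 4.97 (SD, n = 3) against 7.92% ± 4.37 (SD, n = 3). At the invasive site it made up 10.7% in replicate 6 but 1.76% and 2.46% in replicates 4 and 5. Its log odds differed by -0.69, and by -0.21 without cells whose barcode and cluster recur in another library, which are 16 of the 21 Decidua 1 cells in control replicate 3. That exclusion was chosen after the data were seen. Cytotrophoblasts made up 15.5% ± 18.1 (SD, n = 3) against 12.3% ± 12.7 (SD, n = 3). These 5 classes had limma adjusted p-values between 0.468 and 0.954. The difference in mean share changed direction when 1 library was left out in 5 of the 10 classes, which were syncytiotrophoblasts and all of these except Decidua 1. In the log odds, the direction for cytotrophoblasts, extravillous trophoblasts and myeloid cells turned when the 2 smallest libraries were left out.

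**Figure D2:**
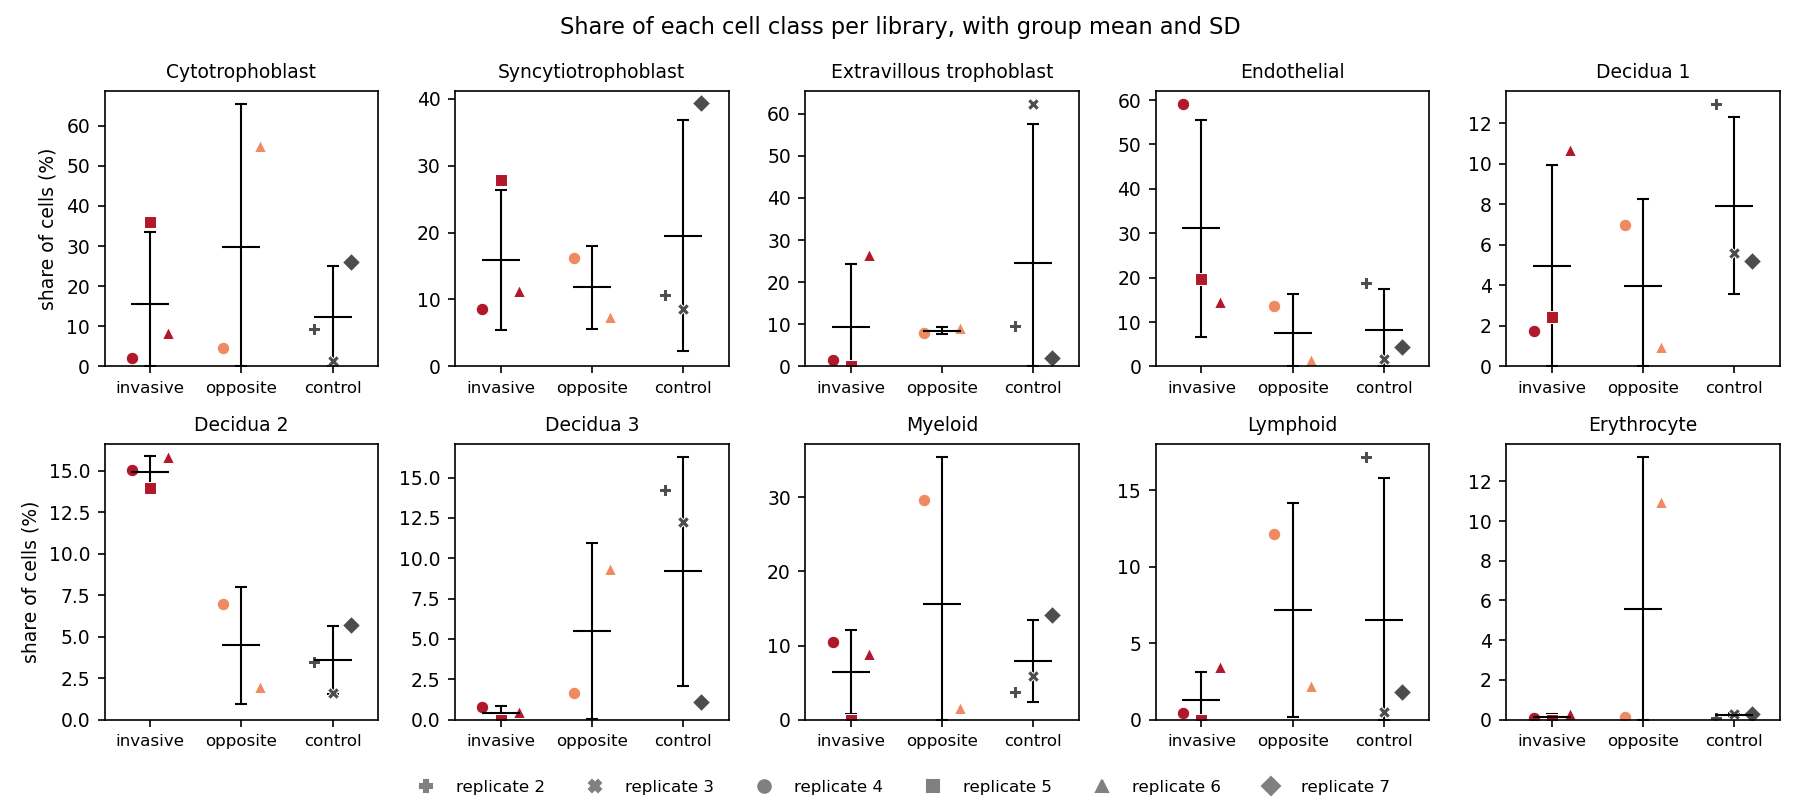
Each panel is 1 cell class, each symbol 1 library (share of its cells in percent, marked by replicate number), and the black line and bar are the group mean and SD, with the bar ending at 0 where the SD exceeds the mean. Decidua 2 lies between 13.9 and 15.8% in the 3 invasive site libraries and at or below 6.98% in the other 5.

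The endothelial share was also compared on its own, because the title names these cells. The 3 invasive site libraries held 59.2% (95% Wilson interval 58.1 to 60.3%), 19.7% (13.6 to 27.6%) and 14.4% (11.9 to 17.3%) endothelial cells for replicates 4, 5 and 6. The control libraries held 18.9% (16.5 to 21.5%), 1.60% (0.735 to 3.45%) and 4.27% (3.92 to 4.64%) for replicates 2, 3 and 7. All 3 invasive site libraries lay above the control mean, by 22.9 percentage points on average. Control replicate 2 lay above invasive site replicate 6, so the groups overlapped, with an exact permutation p of 0.20, two-sided. Without invasive site replicate 4 the mean difference was 8.80 percentage points. When all cells of a group were pooled the shares were 55.3% and 5.21%, a difference of 50.1 percentage points. Invasive site replicate 4 supplied 91.2% of the invasive site cells, and control replicate 7 supplied 90.3% of the control cells.

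The libraries were also split by cell barcodes into 4 that were linked by barcodes carrying the same class (invasive and opposite site replicates 4 and control replicates 2 and 3) and the other 4. Among the linked 4, endothelial cells made up 59.2% in the invasive site library and 10.2% on average in the 2 controls. Among the other 4, they made up 17.0% on average in 2 invasive site libraries and 4.27% in the 1 control. Decidua 2 made up 15.1% against 2.54% within the first set and 14.9% against 5.68% within the second. Decidua 3 made up 0.792% against 13.2% and 0.233% against 1.06%. The 0.233% rests on 0 of 122 and 3 of 645 cells. The limit of 2.46% in invasive site replicate 5 lies above 1.06%, so the second set does not place invasive site below control. With the set as a covariate, chosen after the data were seen, the limma log odds at the invasive site against control were 2.44 for endothelial cells, 1.67 for Decidua 2 and -2.20 for Decidua 3. The adjusted p-values were 0.305, 0.503 and 0.305, and 0 classes passed.

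The opposite site and control libraries overlapped in every class, and the difference in mean share changed direction in 9 of the 10 classes when 1 library was left out. Endothelial cells made up 7.57% ± 8.70 (SD, n = 2) of opposite site libraries, against 8.24% in controls. Decidua 1 made up 3.96% ± 4.27 (SD, n = 2), Decidua 2 4.48% ± 3.54 (SD, n = 2) and Decidua 3 5.49% ± 5.45 (SD, n = 2). Cytotrophoblasts made up 29.9% ± 35.6 (SD, n = 2), syncytiotrophoblasts 11.8% ± 6.21 (SD, n = 2) and extravillous trophoblasts 8.47% ± 0.844 (SD, n = 2). Syncytiotrophoblast, the hormone-secreting outer layer of the villi, made up 19.5% ± 17.2 (SD, n = 3) in controls. Myeloid cells made up 15.6% ± 19.9 (SD, n = 2) and lymphoid cells 7.18% ± 7.0 (SD, n = 2) at the opposite site. Erythrocytes made up 5.55% ± 7.68 (SD, n = 2) at the opposite site and 0.219% ± 0.0986 (SD, n = 3) in controls, a mean set by opposite site replicate 6.

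With limma, 0 of 10 classes passed the threshold between opposite site and control, and 0 had an unadjusted p under 0.05. The log odds differed most for erythrocytes, by 1.59 (SE 1.29) with an adjusted p of 0.941. The smallest two-sided p of the exact permutation tests was 0.30, where 2 against 3 libraries allow 0.10. Without opposite site replicate 6, the log odds of erythrocytes, cytotrophoblasts and endothelial cells turned direction against control.

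Between the 2 accreta sites, endothelial cells and Decidua 2 had higher shares at the invasive site in both placentas sampled at both sites. In the placenta of replicate 4, endothelial cells made up 59.2% of cells at the invasive site and 13.7% (95% Wilson interval 12.7 to 14.8%) at the opposite site, an odds ratio of 9.12. In the placenta of replicate 6 they made up 14.4% and 1.41% (1.12 to 1.78%), an odds ratio of 11.7. Decidua 2 made up 15.1% (14.3 to 15.9%) and 6.98% (6.24 to 7.81%) in the first of these placentas, an odds ratio of 2.36. In the second it made up 15.8% (13.2 to 18.8%) and 1.97% (1.62 to 2.40%), an odds ratio of 9.33. Cytotrophoblasts and Decidua 3 had higher shares at the opposite site of both placentas, with odds ratios of 2.22 and 13.7 for cytotrophoblasts and 2.08 and 22.1 for Decidua 3. Erythrocytes also had the higher share at the opposite site of both, but for replicate 4 this rested on 7 and 5 cells with overlapping intervals.

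The other 5 classes went in opposite directions in the 2 placentas. Myeloid cells made up 10.4% and 29.6% at the invasive and opposite sites of replicate 4, but 8.84% and 1.55% of replicate 6. Lymphoid cells made up 0.453% and 12.1% in the first and 3.41% and 2.23% in the second, where the intervals overlapped. Extravillous trophoblasts made up 1.56% and 7.87%, then 26.5% and 9.07%. Agreement in direction in 5 of 10 classes is the number that chance gives for 2 placentas.

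By observed shares over all libraries, the sites did not overlap in 3 of the 10 classes (endothelial, Decidua 2 and Decidua 3). For endothelial cells the intervals of invasive site replicate 6 (11.9 to 17.3%) and opposite site replicate 4 (12.7 to 14.8%) overlapped. Free relabelling of 3 against 2 libraries gives 20% of classes, but it ignores that 4 of these libraries are pairs from 2 placentas. For Decidua 3 the limit of 2.46% in invasive site replicate 5 lies above the 1.63% of opposite site replicate 4. With limma, 0 of 10 classes passed the threshold between the sites and 0 had an unadjusted p under 0.05. The log odds of endothelial cells differed by 2.11 (SE 1.25) with an adjusted p of 0.416, and those of Decidua 2 by 1.51 (SE 1.17) with the same adjusted p. Two-sided exact permutation p-values were 0.40 for endothelial cells and 0.10 for Decidua 2 and Decidua 3, the smallest that free relabelling of 3 against 2 allows. Exchanging the sites within the 2 placentas sampled at both has 4 arrangements and cannot give a two-sided p under 0.50. A fixed placenta term, chosen after the data were seen, passed no class. The fit with placentas as a block passed none either, but its estimated correlation over classes was negative, so it does not act as pairing.

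**Figure D3:**
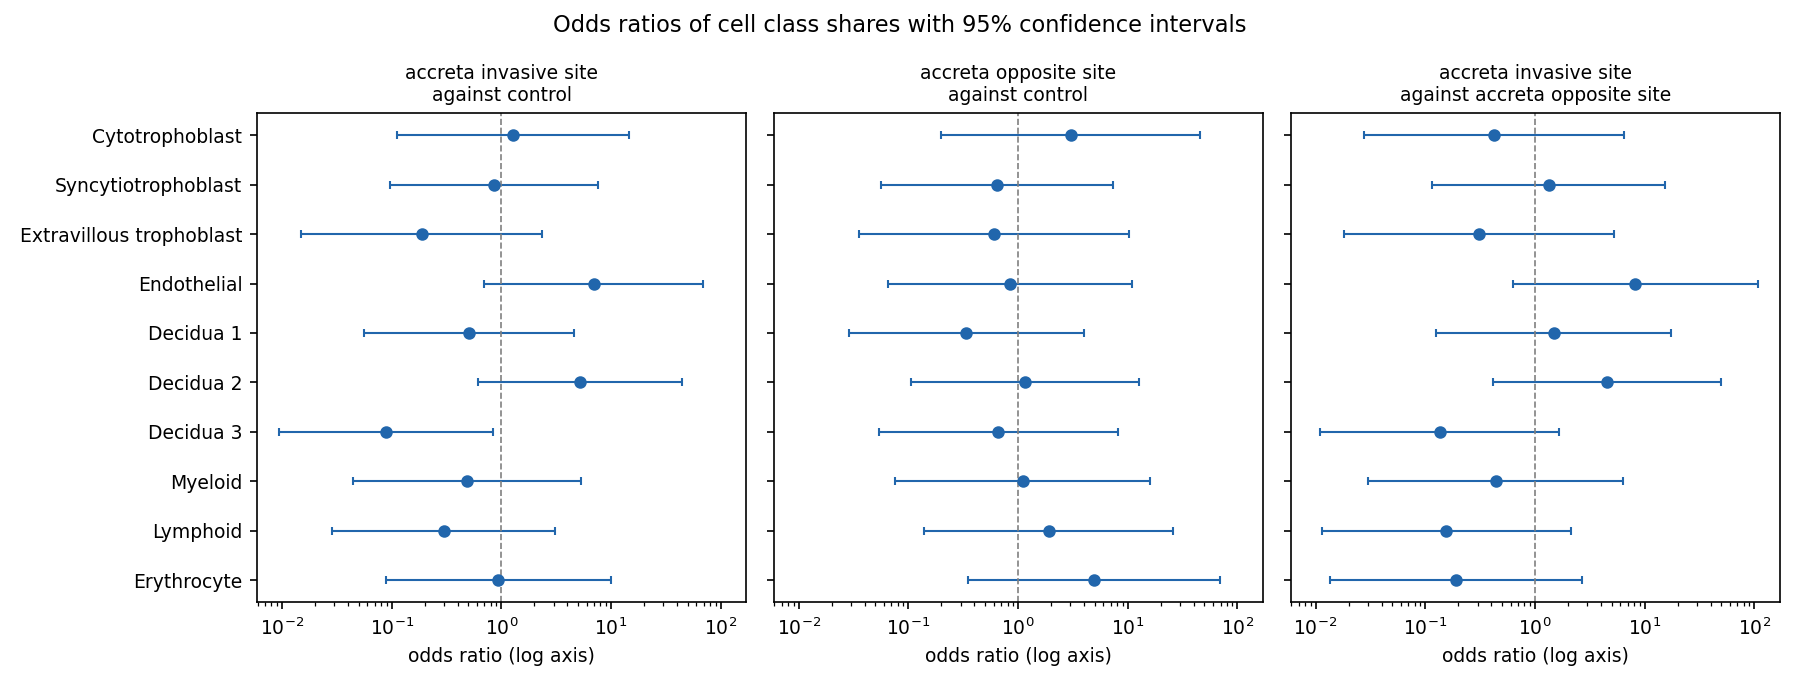
Points are odds ratios of each cell class between 2 groups from limma on logit shares (log axis, 1 marks no difference), and bars are 95% confidence intervals before adjustment for 10 classes. The interval excludes 1 only for Decidua 3 at the invasive site against control, whose adjusted p is 0.356.

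At the level of broad lineages, the decidual classes together made up 20.3% ± 5.79 (SD, n = 3) of invasive site cells, 13.9% ± 2.36 (SD, n = 2) of opposite site cells and 20.7% ± 9.42 (SD, n = 3) of control cells. Trophoblast made up 40.7% ± 26.2 (SD, n = 3), 50.2% ± 30.2 (SD, n = 2) and 56.4% ± 23.4 (SD, n = 3) in the same order. The endothelial, myeloid, lymphoid and erythrocyte lineages each hold 1 class and have the shares given above. With limma over the 6 lineages, 0 passed the threshold and 0 had an unadjusted p under 0.05 in each of the 3 comparisons. The adjusted p-values lay between 0.430 and 0.971. Without opposite site replicate 4, which leaves opposite site replicate 6 alone and assumed to vary like the other groups, erythrocytes passed the threshold against control (adjusted p = 0.0273) and against the invasive site (adjusted p = 0.0243).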

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

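All tests in this part were chosen after the result was seen. Cell barcodes, which no planned comparison uses, recurred between libraries, and each barcode is counted once here. Of 119 barcodes in at least 2 libraries, 31 had the same class in at least 2, where 10000 draws from each library's makeup gave 18.8 on average and 33 at most (permutation p = 0.0013). The division by number of libraries, and a permutation p of 0.05 as the bound, were chosen after this count and that of barcodes in at least 3 libraries were seen. Of 14 barcodes in at least 3 libraries, 12 stood in the same cluster in at least 3. Chance collisions of barcodes are argued against for these 12, since the draws gave 3 at most (permutation p = 0.0001, the smallest these draws can give). For the 105 barcodes in exactly 2 libraries, chance collisions are a candidate explanation. Of these, 17 had the same class in both, and the draws gave 12.1 on average and 26 at most (permutation p = 0.0920). Of the 12, 11 stood in the same cluster in all 4 of invasive site replicate 4, opposite site replicate 4 and control replicates 2 and 3. Whether molecules were carried over between these 4 libraries cannot be told apart from other origins of the 12 barcodes, because reads and UMIs were not used here. Cells that share barcode and cluster number 79, of which 66 are in these 4 libraries and 13 in the other 4. Of the 66, 54 are Decidua 1, and in control replicate 3 these are 16 of the 21 Decidua 1 cells. No biological explanation was tested.

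Some numbered clusters took a share of their class in an accreta library whose 95% Wilson interval lay above those of all control libraries with at least 20 cells of the class. This covers counting error only, and no gene values were used to say what the clusters are. Cluster 18 made up 58.2% of the syncytiotrophoblasts in opposite site replicate 4, against at most 15.6% in a control library, and none of the 374 in opposite site replicate 6. Cluster 3 made up 73.3% of the myeloid cells and cluster 12 made up 32.3% of the cytotrophoblasts in that library, against at most 51.4% and 21.8% in a control library. In opposite site replicate 6 these were 61.5% and 2.68%. Cluster 11 made up 54.2% of the endothelial cells in invasive site replicate 5 (13 of 24 cells) and 24.7% in invasive site replicate 6, against at most 13.5% in a control library. In invasive site replicate 4 it made up 15.4% (14.4 to 16.5%), which overlaps that control library (10.9 to 16.7%). Cluster 21 made up 31.8% of the Decidua 3 cells in opposite site replicate 6, against at most 16.0% in a control library and 1.52% in opposite site replicate 4.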

How the results depend on the processing

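The number of classes past the threshold stayed at 0 in all 3 comparisons under the 24 alternatives run, of which the filter at 100 cells removed no class and so tests nothing. The fixed placenta term leaves invasive site replicate 5 (122 cells) as the only accreta library that carries the comparisons with control, and leaving out either opposite site library leaves 1 at that site, so these say little. The smallest adjusted p among them was 0.0640. For endothelial cells at the invasive site against control the adjusted p ran from 0.192 to 0.798, for Decidua 2 from 0.108 to 0.798 and for Decidua 3 from 0.0734 to 0.743, with no change of direction. With placentas as a block by an estimated correlation (-0.375 over classes, 0.264 over lineages), 0 classes and 0 lineages passed and no call changed. In this block fit with limma the log odds of endothelial cells between the sites was 2.02 (adjusted p = 0.598). A negative correlation treats libraries of the same placenta as less alike than others, so 2.02 is not a paired difference. Not run, because they need UMIs, mitochondrial shares or a column of counts, were the filters on these, the count models and every alternative of the UMI results.

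The endothelial difference against control was 22.9 percentage points and 50.1 when cells were pooled, since pooling weights libraries by cells. Leaving out 1 library gave 8.80 to 31.2, and none of its exact tests could fall under 0.05. Lineage counts against control at the opposite site, and between sites, ran from 0 to 1 with 1 library left out, the 1 being erythrocytes without opposite site replicate 4. The cause was not tested.

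Of 588 values of single classes and of the trophoblast and decidua lineages under alternatives, 551 kept their direction and side of the threshold and 37 reversed, with no call gained or lost. The cause was not tested. The alternatives without the 2 smallest libraries, with the library set and with a fixed placenta term were chosen after the data were seen. In log odds for invasive site against control, leaving out the 2 smallest libraries gave -1.46 for cytotrophoblasts, 0.49 for extravillous trophoblasts and 0.29 for myeloid cells, and the library set gave -0.60 for cytotrophoblasts. For decidua the arcsine gave -0.000267. For opposite site against control, leaving out the 2 smallest gave 0.69 for extravillous trophoblasts, -0.10 for lymphoid cells and 0.078 for trophoblast, the library set 0.081 for endothelial cells, shares within the lineage 0.16 for Decidua 3, and a fixed replicate block, resting on invasive site replicate 5, -0.51 for lymphoid cells and 0.83 for syncytiotrophoblasts. Between sites, leaving out the 2 smallest and the fixed block each gave 0.26 for myeloid cells.

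With 1 library left out, log odds for invasive site against control ran from -0.61 to 1.02 for cytotrophoblasts, -1.31 to 0.36 for myeloid cells and -0.27 to 0.32 for decidua. For opposite site against control they ran from -0.51 to 2.71 for cytotrophoblasts, -1.33 to 0.49 for Decidua 3, -1.37 to 1.03 for endothelial cells, -0.66 to 3.85 for erythrocytes, -1.51 to 0.69 for extravillous trophoblasts, -0.25 to 1.62 for lymphoid cells, -0.88 to 0.16 for syncytiotrophoblasts and -1.18 to 0.65 for trophoblast. Between sites they ran from -2.46 to 0.75 for cytotrophoblasts, -3.91 to 0.59 for erythrocytes, -2.46 to 0.82 for myeloid cells and -1.44 to 0.39 for trophoblast.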

Other observations

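All tests in this part were chosen after the result was seen. Within classes, the clusters were also compared by number. Endothelial cells fall in 7 clusters. Cluster 13 made up 5.11% ± 4.59 (SD, n = 3) of the endothelial cells at the invasive site, 17.7% ± 7.12 (SD, n = 2) at the opposite site and 20.7% ± 11.9 (SD, n = 3) in controls, of which control replicate 3 holds only 6 endothelial cells. Without that library the control mean was 14.4%, and without invasive site replicate 5, with none of 24 cells, the invasive site mean was 7.67%. Without invasive site replicate 4 it was 3.23%. Cluster 11 made up 31.4% ± 20.2 (SD, n = 3), 8.81% ± 1.48 (SD, n = 2) and 13.2% ± 3.59 (SD, n = 3) in the same order. Without invasive site replicate 5 (13 of 24 cells) the invasive site mean of cluster 11 was 20.1%. Syncytiotrophoblasts of cluster 18 made up 25.8% ± 13.7 (SD, n = 3) of their class at the invasive site and 5.55% ± 8.74 (SD, n = 3) in controls, or 0.516% without control replicate 3 (5 of 32 cells). With limma over 20 clusters, 0 passed an adjusted p of 0.05 in each of the 3 comparisons and 0 had an unadjusted p under 0.05. Invasive site replicate 5 holds no myeloid or Decidua 3 cells, so the added 0.5 alone set the log odds of their clusters there to 0. Cluster 24, with no cell at either accreta site, thus got an odds ratio of 4.70 at the invasive site over control. The estimates of these clusters at the invasive site are not read, and they also enter the shared spread and the adjustment. The smallest unadjusted limma p was that of cluster 13 between invasive site and control, with an adjusted p of 0.580. Cluster 23, with 41 cytotrophoblasts, was seen in opposite site replicate 6 alone, and cluster 24, with 28 Decidua 3 cells, in control replicate 2 alone.

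The endothelial share was higher at the invasive than at the opposite site in both placentas with both sites, a pattern picked from 10 classes of which 5 agreed in direction. Cells that share barcode and cluster are too few to account for it. They hold 2 of the 4706 endothelial cells at the invasive site of replicate 4 and 2 of the 554 at its opposite site. None of them are endothelial in replicate 6. Without them the smaller odds ratio was 9.16, against 9.12 with them, a value that so few cells could hardly move. Fewer recovered trophoblast cells alone do not give it, since among cells that are not trophoblast the smaller odds ratio was 6.97. That value, for replicate 6, also depends on other classes. Erythrocytes and Decidua 3 made up 38.6% and 32.9% of these cells at its opposite site, against 0.575% and 0.862% at its invasive site. How far those 2 classes account for the endothelial difference in replicate 6 was not tested. A difference between library sets cannot be told apart for the placenta of replicate 6, whose libraries share a set only by not being linked. A difference in biology between the sites, how deep each biopsy reached and which cells survived freezing stay open and untested, and an exact test over 2 placentas cannot pass.

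The pooled endothelial shares, 55.3% at the invasive site and 5.21% in controls, differ 10.6-fold. Pooling weights libraries by cells, and these shares lie close to the 59.2% of invasive site replicate 4 and the 4.27% of control replicate 7. That weighting by itself takes the ratio from 3.77 with equal weight per library to 10.6. Whether a ratio above the bound of 1.5 remains without these 2 libraries cannot be told. The remaining pools are again mostly 1 library (84.1% and 71.7% of their cells), and 2 weightings disagree about that bound. Without the largest library of each group the pooled shares were 15.3% of 767 cells and 14.0% of 1324 cells, a ratio of 1.09. With equal weight per library the same 4 libraries gave 17.0% and 10.2%, a ratio of 1.67, and all 6 libraries gave 3.77. Whether invasive site replicate 4 differs by its tissue or by its preparation stays open.

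The libraries of the invasive site and control make 10 splits into groups of 3, too few for a share under 0.05. A real count of 0 also fixes the outcome, since every split then has at least as many, so these counts test nothing. For cell classes the real split had 0 past the threshold and the highest other had 1, and 10 splits had as many as the real one. For lineages the real split had 0 and the highest other had 0, again with 10 splits as high. The split with 1 class set invasive site replicates 4 and 5 and control replicate 7 against the rest, and the class was extravillous trophoblast.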
